A study of Rattus norvegicus with 16 samples.

How the data were processed

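RNA of intestinal smooth muscle from rats was measured on 16 single-colour Agilent arrays, 4 in each of 4 groups. The groups are control, RESUS, VH and RESUS+VH. The sample descriptions call the last group EDEMA. The labels do not expand RESUS and VH. Per the labels' protocols, the distal part of the intestine was collected immediately after sacrifice and frozen in liquid nitrogen, and total RNA was amplified and labelled with Cy3. The protocol's wording on the longitudinal muscle can mean that this layer was collected or that it was removed, so the layer measured is not settled.

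The deposited scanner files hold the intensity of 45018 spots per array, made with Agilent Feature Extraction 9.1.3.1, per the file headers. Of these, 43379 spots carry 41012 probes that are not controls. The column used holds the processed signal, which is the intensity after the scanner software's own background subtraction, per the file headers. The deposited series matrix holds 1 value per probe and array, and its scale is not stated in the labels. All 41012 matrix probes matched a probe of the scanner files. On every array at least 98.2% of the compared probes equalled the processed intensity divided by 1 constant per array, within 0.02 on the log2 scale. The constants ran from 93.0 to 186.5, and intensities had a floor between 4.94 and 5.07. The matrix is thus on a linear scale with no centring of genes, and what the constants stand for stays unknown. Its column medians were 0.288, 0.384, 0.342 and 0.371 in control, 0.395, 0.416, 0.368 and 0.413 in RESUS+VH, 0.332, 0.311, 0.321 and 0.356 in VH, and 0.405, 0.448, 0.400 and 0.450 in RESUS.

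Spots of the same probe were averaged on the log2 scale and outlier spots were left out. Each array's 75th percentile of log2 processed intensity over non-control probes was subtracted. A probe counted as well above background where at least 0.5 of its spots were. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which left 28776 probes. A gene with several probes was represented by the probe with the highest mean over the 16 arrays, which left 24815 genes, of which 3298 had several probes. Of the 41012 probes, 10735 were named through an accession in a gene table of assembly GRCr8, 5571 kept a gene symbol from the files, and 24706 had only another name from the files. Among the genes tested 9983 (40.2%) carried a gene symbol, so the larger part of each gene count below has no gene name. For 493 genes a value was missing on some array, and set tests used the 24322 complete genes.

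All 16 arrays entered 1 linear model of group means with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 12 residual degrees of freedom. The 6 comparisons were RESUS+VH, VH and RESUS against control, RESUS+VH against VH, RESUS+VH against RESUS, and the interaction, which is the RESUS+VH minus VH difference less the RESUS minus control difference. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all genes, and every adjusted p given for a gene is limma's. Log2 differences are given with their standard error (SE). Where no array of a group had any probe of a gene well above background, a fold is given as "at least". It compares the brighter group's mean with a mean over the dim group's arrays. On each of those arrays the higher of the gene's signal and the lowest signal among probes well above background was taken. A gene thus counted as above background where any of its probes did, even if the probe representing it did not.

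Gene names given in the text follow a rule fixed before the data were examined. For comparisons with control these are the 10 largest rises and 10 largest falls among called genes with a symbol whose arrays do not overlap between the groups, and for the others 5 of each, without the rule on overlap for the interaction. From each gene list up to 4 called members with the largest change are eligible, or 2 members with the smallest p where none was called. Actg2, Myh11, Stat3 and Nfkbia were always reported, and Acta2 was not named on the array. Some genes the rule selects are not reported here. The 43 gene lists, 28 of pathways and 15 of cell types, were fixed at the same time. Some genes belong to several lists, so the list results are not independent of each other. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 43 lists within a comparison, and again with an estimated correlation. Counts of members "adjusted over the list alone" apply Benjamini-Hochberg within the list.

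Each group lies on its own slide of 4 arrays, and each slide was scanned separately. Slide, scan and group therefore cannot be told apart, and neither slide nor scan was used as a block. By consecutive slide codes in the file headers the slides form 2 pairs, with control and RESUS+VH in the first and VH and RESUS in the second. Their mean local backgrounds were 55.2 and 55.7 in the first pair and 48.8 and 48.2 in the second. The labels do not say that each array is a separate animal, so the p-values measure only the spread between these samples. The replicate numbers were not used as pairs.

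The alternatives fixed before the data were examined were quantile and median normalization, normexp background correction (offset 50), the series matrix values, no filter and a stricter filter on dim probes, other rules for several probes, fits of only the groups compared, trend and robust variance, array weights, a replicate block, the number in the description as a covariate, leaving out each array, and fry or an estimated correlation for the lists. Those chosen after seeing the data were the mean of the epithelium list as a covariate, leaving out the 3 arrays lowest in it, the slide pair as a block, and 3 other forms of normexp, tried because the planned form called few genes. The fit was tested on data simulated for RESUS+VH against control over 24322 genes, 200 of them changed. It recovered 0%, 30%, 84% and 98% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, and 5 of 111 calls (4.5%) were unchanged genes. The real comparison called 3498 genes, which loosens the Benjamini-Hochberg cutoff, so these shares do not carry over to it. The simulated noise was independent between genes and arrays and held no slide effect. Scanner files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.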

Results

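The arrays measured gene expression in rat intestinal smooth muscle in control animals, under RESUS, under VH, and under both together. In studies of intestinal edema these abbreviations commonly stand for fluid resuscitation and mesenteric venous hypertension, but the labels do not spell them out. The series title names the effects of edema on the muscle as its subject. The share of probes well above background was 67.7% ± 3.39 (SD, n = 4) in control, 71.4% ± 1.08 in RESUS+VH, 66.8% ± 1.48 in VH and 73.1% ± 1.53 in RESUS, and no spot was saturated. The 75th percentile of intensity was 283 ± 74.5 in control, 361 ± 33.6 in RESUS+VH, 220 ± 31.8 in VH and 386 ± 44.6 in RESUS. The median correlation between arrays of a group was 0.964 in control, 0.961 in RESUS+VH, 0.963 in VH and 0.979 in RESUS. The number of arrays limits the precision. Each group lies on its own slide, so every difference below is also a difference between slides.

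**Figure D1:**
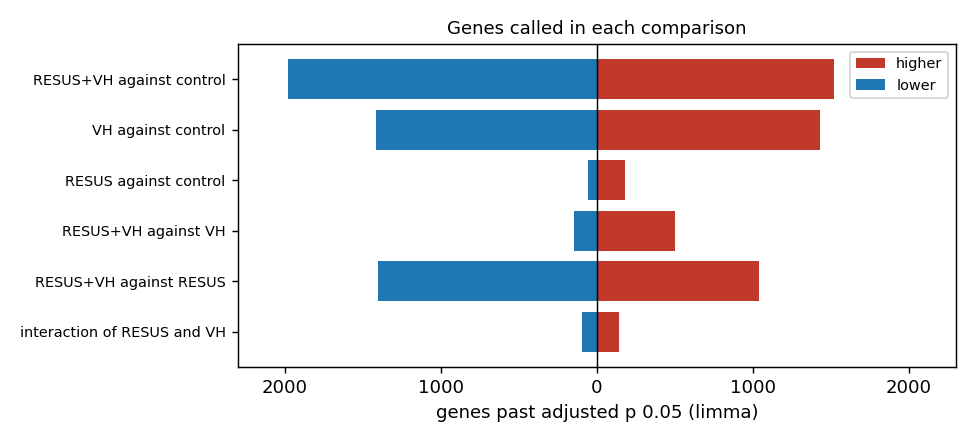
Number of genes past an adjusted p of 0.05 (limma) in each of the 6 comparisons, with genes higher to the right of 0 and genes lower to the left. The 3 comparisons of a VH group with a group without VH hold the most genes, with 3498, 2847 and 2442.

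The comparison of RESUS+VH with control asks how muscle expression differs in the group described as edema. Of 20 inflammatory genes 14 rose, of 24 STAT3 and IL-6 responsive genes 14, and of 15 neutrophil genes 10. Among genes of muscle contraction 5 of 19 fell, of channels and calcium handling 7 of 28, of oxidative phosphorylation 7 of 38 and of fatty acid oxidation 6 of 26. Of the 43 lists 16 were called, and 0 with an estimated correlation (smallest adjusted p = 0.363 with an estimated correlation). In all, 1520 genes rose and 1978 fell, and 4704 genes (19.1%) had no overlap between the arrays of the groups, against 2.86% by chance. The higher share of calls was 43.5%, and it was 31.7% with median normalization. It was 32.3% with normexp without spots far below their local background and 30.8% with normexp on all spots. Without RESUS+VH 4 the number of genes called was 1982. It was 156 with normexp on all spots, 1998 with the description number as a covariate and 1561 with only the groups compared.

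Largest changes here and below are ranked among genes that meet the naming rule, with its condition on overlap of arrays where it applies. They are also limited to genes well above background on some array of each group compared. For genes without such an array in a group a bound is given without a rank. The largest rises in RESUS+VH were those of the chemokine Cxcl1, by 5.78 ± 0.67 (SE, log2; adjusted p = 0.000764), and of the transcription factor subunit Fosl1, by 5.19 ± 0.76 (adjusted p = 0.00158). They were followed by Ccl17 (4.75), Csrp3 (4.61), Cxcl2 (4.43), S100a8 (4.40), Il1r2 (4.25), Plet1 (4.02), Steap1 (3.75) and Fcnb (3.70). The largest falls were those of Slco1a4, by -2.51 ± 0.35 (adjusted p = 0.00144), and Gtf2a1l (-2.38). They were followed by Apobec2 (-2.31), Omd (-2.08), Cox8b (-2.03), the clock repressor Nr1d1 (-2.01), Mmp11 (-1.94) and the adrenergic receptor Adrb3 (-1.94). Omd rests on RESUS+VH 1 (-6.30, others -3.23 to -2.93), and without that array its difference was -1.26 and did not pass (adjusted p = 0.0515). The potassium channel Kcnn2 was not well above background in RESUS+VH and was at least 1.68-fold lower, with a log2 difference of 0.095 with normexp on all spots. Lrrc17 was likewise at least 3.63-fold lower.

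**Figure D2:**
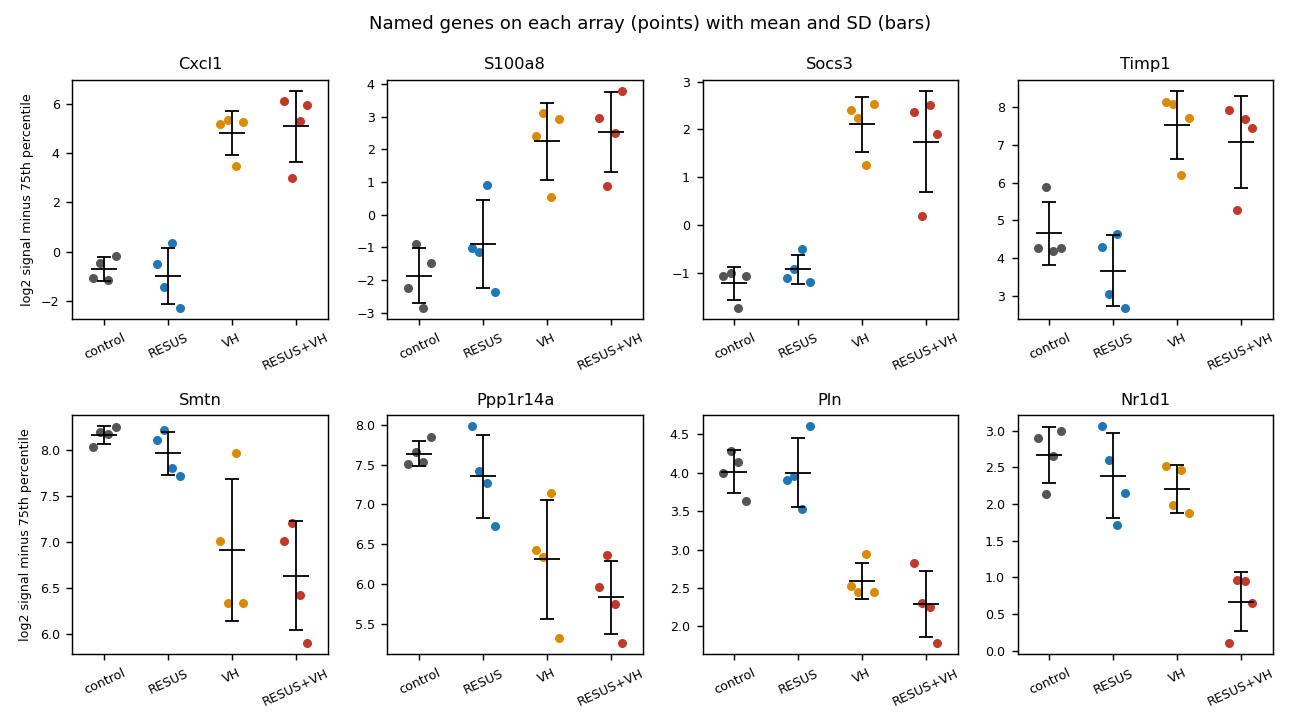
Log2 intensity minus the array's 75th percentile for 8 named genes, with each array as a point and the group mean and SD as bars. Cxcl1 was higher by 5.78 in RESUS+VH and by 5.52 in VH than in control on the log2 scale.

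Of the 20 measured inflammatory cytokine, chemokine and adhesion genes, 14 rose in RESUS+VH and 0 fell (16 rose adjusted over the list alone). Their median was 2.23, or 1.996 with members not well above background at their bound (camera adjusted p = 3.41e-09, adjusted p = 0.363 with an estimated correlation). Of 18 NF-kB targets 9 rose (12 adjusted over the list alone), with a median of 1.13 (adjusted p = 7.35e-08, adjusted p = 0.425 with an estimated correlation). Ccl2 (3.24), Nfkbiz (3.23) and Birc3 (2.59) were among them, and Nfkbia rose by 1.06 ± 0.25. Of 24 STAT3 and IL-6 responsive genes 14 rose (18 adjusted over the list alone), with a median of 1.40 (adjusted p = 3.64e-08, adjusted p = 0.363 with an estimated correlation). The RESUS+VH 2 array showed less of this rise, with scores of 0.65 for the inflammatory list (others 2.35 to 3.29), 0.18 for NF-kB targets (others 1.17 to 1.54) and 0.47 for the STAT3 list (others 1.33 to 1.55). The STAT3 list included Socs3 (2.95), Timp1 (2.43) and Spp1 (2.24), and Il6, which was not well above background in control, was at least 3.35-fold higher. Stat3 itself rose by 0.96 ± 0.25 (adjusted p = 0.021), a difference that was -0.16 with normexp on all spots. Of 15 neutrophil genes 10 rose (10 adjusted over the list alone), with a median of 1.51 (adjusted p = 6.08e-06, adjusted p = 0.363 with an estimated correlation). These lists share members, such as Cxcl1 and Ccl2 (inflammatory and NF-kB), Il6 (inflammatory and STAT3) and Lcn2 (STAT3 and neutrophil). Their rises are thus not separate lines of evidence.

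Of 19 genes of the smooth muscle contractile apparatus 5 fell in RESUS+VH and 0 rose (6 fell adjusted over the list alone), with a median of -0.40 (adjusted p = 0.00317, adjusted p = 0.595 with an estimated correlation). Smoothelin (Smtn) changed by -1.53 ± 0.34, leiomodin (Lmod1) by -1.31 ± 0.27 and Dmn, which encodes synemin, by -1.04 ± 0.29. Actg2 (-0.16, adjusted p = 0.841) and Myh11 (-0.63, adjusted p = 0.133) did not pass the test. In the control of myosin light chain phosphorylation, the kinase Mylk fell (-0.91) and so did the phosphatase inhibitor Ppp1r14a (-1.81), while the kinase Rock2 rose (1.63). That list of 21 did not pass as a whole (adjusted p = 0.77), and its median of 0.01 differs in sign from its mean of -0.08 and its test. Of 28 ion channel and calcium handling genes 7 fell (8 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.00317, adjusted p = 0.499 with an estimated correlation). The calcium pump regulator phospholamban (Pln) changed by -1.73 ± 0.25 and the sodium-calcium exchanger Slc8a1 by -0.99 ± 0.30. Among 24 motility receptors 3 rose and 2 fell, with the bradykinin receptor Bdkrb1 up by 3.02 and the tachykinin receptors Tacr2 and Tacr1 at -1.67 and 0.71.

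Of 38 oxidative phosphorylation genes 7 fell in RESUS+VH (10 adjusted over the list alone), with a median of -0.34 (adjusted p = 6.46e-05, adjusted p = 0.489 with an estimated correlation). Of 26 genes of fatty acid oxidation and PPAR targets 6 fell (9 adjusted over the list alone), among them Ech1 (-1.26), Cpt1b (-1.09) and Fabp3 (-1.06). That list's median was -0.52 (adjusted p = 0.000477, adjusted p = 0.489 with an estimated correlation). Enteric neuron genes had a median of -0.37 (adjusted p = 0.000551, adjusted p = 0.558 with an estimated correlation), and 5 of 28 fell (5 adjusted over the list alone), including Prph (-0.90) and Uchl1 (-0.70). Blood and lymphatic endothelium had a median of -0.41 (adjusted p = 0.0287, adjusted p = 0.595 with an estimated correlation), and 4 of 22 fell (4 adjusted over the list alone), including Tie1 (-1.21) and Sox18 (-1.08). Beside these groups, the markers of mucosal epithelium did not pass (median 0.13, adjusted p = 0.879). Their scores were -3.57 on RESUS+VH 3 (others 0.34 to 1.94), -2.57 on control 4 (others 0.69 to 1.24) and -1.51 on VH 1 (others 0.42 to 0.94), so this list was uneven within groups. In enteric glia Gfap rose (1.77), and the list did not pass (adjusted p = 0.298).

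Further lists were higher in RESUS+VH. Immediate early genes had a median of 0.38 (adjusted p = 0.00317, adjusted p = 0.499 with an estimated correlation), with 5 of 29 up and 1 down. The cell cycle list had a median of 0.80 (adjusted p = 0.00317, adjusted p = 0.595 with an estimated correlation), with 2 of 32 up. Its scores on the RESUS+VH arrays ran from -0.72 on RESUS+VH 3 to 1.96 on RESUS+VH 1, against -0.40 to 0.49 in control. Without RESUS+VH 3 its median was 1.22, without RESUS+VH 1 it was 0.42, and without RESUS+VH 2 the list did not pass (adjusted p = 0.0737). The p53 and apoptosis list had a median of 0.33 (adjusted p = 0.0135, adjusted p = 0.363 with an estimated correlation), with 4 of 22 up and 1 down. Matrix proteases and inhibitors had a median of 0.46 (adjusted p = 0.0374, adjusted p = 0.501 with an estimated correlation). The glucocorticoid response had a median of 0.57 (adjusted p = 0.026, adjusted p = 0.499 with an estimated correlation), and the interferon response 0.41 (adjusted p = 0.0387, adjusted p = 0.719 with an estimated correlation). Interferon scores of RESUS+VH 1 (0.02) and RESUS+VH 2 (-0.17) lay within those of control (-0.27 to 0.34), and without RESUS+VH 3 that list did not pass (median 0.27, adjusted p = 0.319). With each array of the groups compared left out in turn, 11 of the 16 list calls always held. Those of the cell cycle, interferon, glucocorticoid, matrix protease and endothelium lists were lost without some array. Among single genes of other lists Hmox1 rose by 2.49, Hk2 by 1.95, Vegfa by 0.76 and the clock gene Nfil3 by 2.94.

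The other lists did not pass in RESUS+VH against control, with camera adjusted p from 0.065 for hypoxia to 0.965. They were motility receptors, mechanotransduction, extracellular matrix structure, heat shock, the unfolded protein response, oxidative stress and metal response, water and salt transport, circadian clock, MHC class II, complement and coagulation, TGF-beta signalling, angiogenesis and permeability, and ribosomal proteins. Of the cell type lists, interstitial cells of Cajal, PDGFRA fibroblast-like cells, mucosal epithelium, monocytes and macrophages, mast cells and eosinophils, lymphocytes, mesothelium, adipose tissue, exocrine pancreas, red blood cells, and pericytes did not pass either. Median, mean and test differed in sign for 9 lists here. They were myosin light chain phosphorylation, extracellular matrix, heat shock, water and salt transport, circadian clock, complement and coagulation, TGF-beta signalling, angiogenesis, and lymphocytes.

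**Figure D3:**
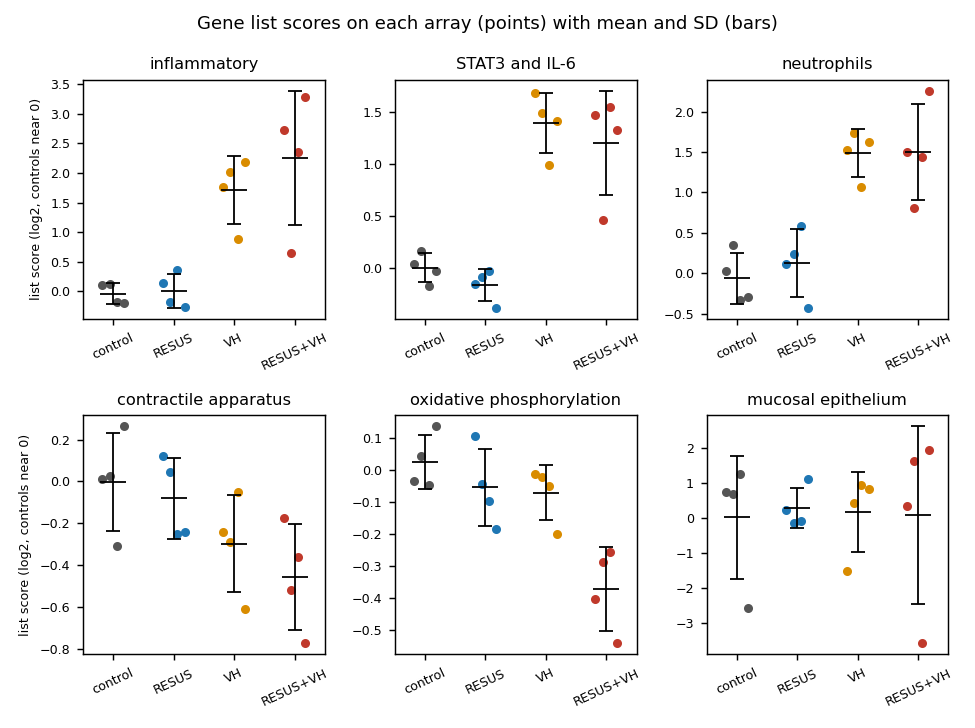
Gene list scores on a log2 scale, where controls lie near 0, with each array as a point and the group mean and SD as bars. The median inflammatory change was 2.23 in RESUS+VH and 1.82 in VH against control.

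The comparison of VH with control asks what VH changes without RESUS. Of 20 inflammatory genes 11 rose, of 24 STAT3 and IL-6 responsive genes 15, and of 15 neutrophil genes 10. Of the 43 lists 17 were called, 14 of them higher, and 0 with an estimated correlation (smallest adjusted p = 0.263 with an estimated correlation). The contractile and oxidative phosphorylation lists did not pass. In all, 1429 genes rose and 1418 fell, and 4435 (18%) had no overlap between arrays, against 2.86% by chance. The higher share was 50.2%, and it was 64.2% with normexp without spots far below their local background and 74% on all spots. The count was 1792, 1740 and 1468 without VH 1, VH 2 and VH 4, and 1806 without control 3. It was 104 with normexp on all spots, 64 with the description number as a covariate and 1181 with only the groups compared.

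The largest rises in VH were those of Cxcl1, by 5.52 ± 0.67 (adjusted p = 0.000529), Fosl1 (5.04), Csrp3 (4.96) and Il1r2 (4.50). Plet1 (4.27), Chrdl2 (4.18), Ptges (4.14), S100a8 (4.11) and Tnfrsf9 (4.10) followed, and Retnlg, not well above background in control, was at least 20.6-fold higher. The largest falls were those of Wfdc18 (-3.74), Tspan18 (-3.01), Slco1a4 (-2.70), Srms (-2.43) and Pde1a (-2.16, and -1.30 without VH 2). Of the genes not well above background in VH, Tp63 was at least 1.74-fold lower, while its mean in RESUS+VH (-3.92) lay near that in control (-3.88). Jrk was at least 3.90-fold lower, Or4a69 2.60-fold, Or4g17 2.38-fold and Kcnc1 2.08-fold, each as a lower bound.

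In VH 11 of 20 inflammatory genes rose (16 rose and 2 fell adjusted over the list alone), with a median of 1.82, or 1.48 with members at their bound (adjusted p = 9.94e-08, adjusted p = 0.379 with an estimated correlation). Of 24 STAT3 and IL-6 responsive genes 15 rose (16 rose and 1 fell adjusted over the list alone), with a median of 1.46 (adjusted p = 3.91e-09, adjusted p = 0.379 with an estimated correlation). Stat3 rose by 1.62 ± 0.25 (adjusted p = 0.00213) and Socs3 by 3.31 ± 0.42, while Nfkbia did not pass (0.42, adjusted p = 0.28). Neutrophil genes had a median of 1.43 (adjusted p = 3.74e-05, adjusted p = 0.379 with an estimated correlation), with 10 of 15 up (10 adjusted over the list alone). NF-kB targets had a median of 0.68 (adjusted p = 4.84e-05, adjusted p = 0.481 with an estimated correlation), with 6 of 18 up (7 adjusted over the list alone). Monocyte and macrophage genes had a median of 0.39 (adjusted p = 0.00891, adjusted p = 0.62 with an estimated correlation), with 3 of 23 up (6 adjusted over the list alone), including Ccr1 (2.05) and Cd68 (0.79).

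Stress lists were higher in VH, with medians of 0.20 for hypoxia (adjusted p = 0.00881, adjusted p = 0.379 with an estimated correlation) and 0.32 for p53 and apoptosis (adjusted p = 0.00881, adjusted p = 0.263 with an estimated correlation). Oxidative stress and metal response had a median of 0.28 (adjusted p = 0.0154, adjusted p = 0.461 with an estimated correlation), with Hmox1 up by 2.97. Matrix proteases and inhibitors had a median of 0.64 (adjusted p = 0.00881, adjusted p = 0.386 with an estimated correlation), with Adamts9 up by 3.01. The interferon response had a median of 0.44 (adjusted p = 0.00777, adjusted p = 0.62 with an estimated correlation), and the glucocorticoid response 0.42 (adjusted p = 0.0317, adjusted p = 0.525 with an estimated correlation). The cell cycle list had a median of 0.34 (adjusted p = 0.0402, adjusted p = 0.74 with an estimated correlation), ribosomal proteins 0.13 (adjusted p = 0.0317, adjusted p = 0.74 with an estimated correlation) and immediate early genes 0.03 (adjusted p = 0.0488, adjusted p = 0.62 with an estimated correlation). With each array of the groups compared left out in turn, 10 of the 17 list calls always held. Those of the cell cycle, ribosomal, immediate early, glucocorticoid, monocyte, enteric neuron and channel lists were lost without some array.

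Fatty acid oxidation and PPAR targets were lower in VH, with 5 of 26 down (6 adjusted over the list alone) and a median of -0.43 (adjusted p = 0.00881, adjusted p = 0.554 with an estimated correlation). Ion channels and calcium handling had a median of -0.24 (adjusted p = 0.0488, adjusted p = 0.62 with an estimated correlation). Of its 28 members Pln (-1.43) and 1 other fell, and the potassium channel Kcnj8 rose by 1.497. VH 4 had the lowest score (-0.60, others -0.18 to -0.11), and without it the list did not pass (median -0.08, adjusted p = 0.208). Enteric neurons had a median of -0.34 (adjusted p = 0.0352, adjusted p = 0.74 with an estimated correlation). The contractile apparatus did not pass (median -0.18, adjusted p = 0.0928), with 3 of 19 genes down, namely Smtn (-1.25), Mylk (-0.94) and Lmod1 (-0.92), a difference that was 0.08 for Lmod1 with the description number as a covariate. Ppp1r14a fell by -1.33 and Rock2 rose by 1.68, as in RESUS+VH, and Actg2 (0.47, adjusted p = 0.515) and Myh11 (-0.74, adjusted p = 0.0934) did not pass. Oxidative phosphorylation did not pass (median -0.09, adjusted p = 0.35). In the clock list Nfil3 (3.13) and Bmal1 (1.90) rose and Bhlhe41 (-1.77) and Dbp (-1.33) fell.

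The comparison of RESUS with control asks what RESUS changes without VH. Few genes changed, and the inflammatory and muscle lists did not pass. The test called 183 genes higher and 55 lower, and only 22 and 18 of these had a gene symbol. At an unadjusted p of 0.05 the number was 2571 genes, and 1906 genes (7.8%) had no overlap between arrays, against 2.86% by chance. The higher share was 76.9%, and it was 60.1% with normexp without spots far below their local background. The count was 156, 130 and 119 without RESUS 1, RESUS 2 and RESUS 3, and 359 without control 4. It was 141 with only the groups compared and 1520 with array weights. In limma it was 0 with normexp on all spots and 0 with the description number as a covariate, where 652 and 1172 genes had an unadjusted p under 0.05.

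Among genes above background in both groups Rps26 rose most in RESUS, by 3.44 ± 0.40 (adjusted p = 0.000444), followed by Nudt9 (2.49), Kcnh2 (2.20), Ccr1l1 (1.69), Snrpe (1.55) and Rpl37al2 (1.47). The control mean of Rps26 (-5.56) lay below that of Retnlg (-5.09), so its rise and rank may rest on signal near background. Rps26 was at -2.15 in RESUS+VH and -2.43 in VH, close to the -2.13 in RESUS. Retnlg, Pecr and Exosc7 were not well above background in control and were at least 6.31-fold, 4.90-fold and 2.30-fold higher. Among genes above background in both groups the falls were led by Or10q12 (-2.16), Eif4g3 (-2.00), Haao (-1.63), Dlk1 (-1.47), Klra5 (-1.39), Or7g24 (-1.32) and Lgi3 (-1.26). In RESUS+VH the means of Or10q12 (-1.91) and Eif4g3 (2.48) lay near those in control (-1.75 and 2.58). In VH they were lower (-3.44 and 1.40), so both genes follow the slide pairs. Tp63, with the smallest p of the comparison (adjusted p = 8.04e-06), and Il12rb1 were not well above background in RESUS and were each at least 2.11-fold lower, and Or4a2 was at least 2.53-fold lower, a log2 difference of 0.04 with normexp on all spots. Tp63 follows the slide pairs likewise, with -3.88 in control and -3.92 in RESUS+VH, and no array well above background in VH or RESUS. Stat3 (0.23), Nfkbia (-0.07), Actg2 (0.46) and Myh11 (-0.12) did not pass, with adjusted p of 0.831, 0.961, 0.799 and 0.931.

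Of the 20 inflammatory genes 0 were called in RESUS, with a median of -0.01 and a mean of -0.04, against the upward sign of the test (adjusted p = 0.841), and 1 rose adjusted over the list alone. The contractile apparatus (median -0.12, adjusted p = 0.841) and oxidative phosphorylation (median -0.04, adjusted p = 0.425) did not pass. Immediate early genes were lower than other genes (median -0.36, adjusted p = 0.0234, adjusted p = 0.981 with an estimated correlation), with 0 of 29 called. Ribosomal proteins were lower (median -0.17, adjusted p = 0.0281, adjusted p = 0.981 with an estimated correlation), but their median was 0.08 with quantile normalization and 0.11 with the description number as a covariate. Among the members of all 43 lists a single gene was called, the collagen Col6a3 (1.16). Rps26, which rose, was not a member of the ribosomal list. Both list calls were lost when some single array was left out.

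The comparison of RESUS+VH with VH asks what RESUS adds in the presence of VH. The inflammatory response did not differ past the threshold, and most called genes carry no gene symbol. The test called 503 genes higher and 147 lower, of which 76 and 56 had a symbol, and 2836 genes (11.5%) had no overlap between arrays, against 2.86% by chance. The direction of these calls depended on the scaling, with a higher share of 77.4%, 54.8% with median normalization and 24.6% with normexp without spots far below their local background. The count was 428, 375 and 416 without RESUS+VH 1, RESUS+VH 2 and RESUS+VH 3, and 408 without VH 1. It was 1279 with normexp without spots far below their local background, 371 with the description number as a covariate, 402 with the stricter filter and 247 with only the groups compared. With normexp on all spots it was 0 in limma, and 1637 genes had an unadjusted p under 0.05.

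Of the 5 largest fitted rises only that of Or10a5 (2.52) was above background in both groups, so the 5 cannot be ranked. The falls were those of Qpct (-2.18), Slc4a7 (-1.65), Ercc5 (-1.59), Bmal1 (-1.55) and Nr1d1 (-1.54). That of Qpct may rest on signal near background, with a RESUS+VH mean of -4.68. Of the genes not well above background in VH, Or4a69 was at least 3.34-fold higher and Gja6 at least 2.05-fold. Tp63 was at least 1.70-fold higher. Efnb1 was at least 1.63-fold higher, with a difference of -0.01 with normexp without spots far below their local background. Rhoa, a regulator of myosin phosphorylation, rose by 0.79 ± 0.16 (adjusted p = 0.0153), Col6a3 by 1.41 and Fos by 1.32. Rhoa follows the slide pairs, with means of 4.30 in control and 4.76 in RESUS+VH against 3.97 in VH and 3.70 in RESUS. Fos does likewise, with 0.20 and 0.70 against -0.62 and -0.42, as do Qpct and Slc4a7 in the other direction. For these genes the difference from VH cannot be told apart from one between the pairs. Stat3 (-0.66, adjusted p = 0.181), Nfkbia (0.64, adjusted p = 0.183), Actg2 (-0.63, adjusted p = 0.48) and Myh11 (0.10, adjusted p = 0.892) did not pass.

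Oxidative phosphorylation was lower in RESUS+VH than in VH (median -0.24, adjusted p = 0.000688, adjusted p = 0.98 with an estimated correlation), with 0 of 38 genes called. With normexp without spots far below their local background its median was -0.18, against -0.17 for all genes, and it did not pass (adjusted p = 0.534). Ribosomal proteins were lower (median -0.28, adjusted p = 0.000403, adjusted p = 0.98 with an estimated correlation), with a median of 0.00 (0.002) under quantile normalization, where they did not pass (adjusted p = 0.858). Monocyte and macrophage genes had a median of -0.44 (adjusted p = 0.00283, adjusted p = 0.98 with an estimated correlation), and red blood cell genes -1.09 (adjusted p = 0.0146, adjusted p = 0.98 with an estimated correlation). The calls of these last lists were lost when some single array was left out. The inflammatory list (median 0.36, adjusted p = 0.339) and the contractile apparatus (median -0.28, adjusted p = 0.215) did not pass.

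The comparison of RESUS+VH with RESUS asks what VH adds in the presence of RESUS. Of 20 inflammatory genes 12 rose, of 24 STAT3 and IL-6 responsive genes 15 and of 15 neutrophil genes 9, while 3 of 19 contractile genes and 6 of 28 channel genes fell. Of the 43 lists 10 were called, and 0 with an estimated correlation (smallest adjusted p = 0.224 with an estimated correlation). The test called 1041 genes higher and 1401 lower, and 5141 genes (21%) had no overlap between arrays, against 2.86% by chance. The count was 1321 and 1191 without RESUS+VH 1 and RESUS+VH 4, and 1416, 1147 and 1305 without RESUS 1, RESUS 2 and RESUS 3. It was 11 with normexp on all spots, 5 with the description number as a covariate and 5220 with array weights. The higher share depended on the scaling, with 42.6%, 33.2% with median normalization, 50.6% with normexp without spots far below their local background and 100% of the 11 on all spots. Among genes counted as free of overlap between the arrays Cxcl1 rose most, by 6.05 ± 0.67 (adjusted p = 0.000522), followed by Ccl17 (4.82), Steap1 (4.79), Cxcl2 (4.46) and Il1r2 (4.24). Fgf23 (-2.60), Fbxl7 (-2.51), Pcdh18 (-2.42) and Kcnh2 (-2.42) fell most, and Kcnn2 was at least 1.73-fold lower. Lcn2 rose by 4.60, more than Cxcl2, but was not counted as free of overlap and so has no rank. Ccl2 (4.08) and Timp1 (3.42) rose, Nfkbia rose by 1.13, and Stat3 did not pass (0.73, adjusted p = 0.0773). Smtn (-1.33), Lmod1 (-1.06), Ppp1r14a (-1.52) and Pln (-1.71) fell, while Rhoa (1.05) and Rock2 (1.33) rose. Rhoa follows the slide pairs, with means of 4.30 in control and 4.76 in RESUS+VH against 3.97 in VH and 3.70 in RESUS. Actg2 (-0.62, adjusted p = 0.384) and Myh11 (-0.51, adjusted p = 0.25) did not pass.

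Against RESUS, 12 of 20 inflammatory genes rose in RESUS+VH (13 adjusted over the list alone), with a median of 2.32, or 2.21 with members at their bound (adjusted p = 2.88e-09, adjusted p = 0.262 with an estimated correlation). STAT3 and IL-6 responsive genes had a median of 1.55 (adjusted p = 6.33e-12, adjusted p = 0.224 with an estimated correlation), with 15 of 24 up (18 adjusted over the list alone). NF-kB targets had a median of 0.98 (adjusted p = 6.14e-08, adjusted p = 0.347 with an estimated correlation) and neutrophil genes 1.58 (adjusted p = 4.74e-07, adjusted p = 0.224 with an estimated correlation). Immediate early genes had a median of 0.82 (adjusted p = 1.57e-07, adjusted p = 0.224 with an estimated correlation), with 8 of 29 up (17 rose and 1 fell adjusted over the list alone). The contractile apparatus had a median of -0.51 (adjusted p = 0.00275, adjusted p = 0.685 with an estimated correlation), and channels and calcium handling -0.54 (adjusted p = 0.000625, adjusted p = 0.386 with an estimated correlation). Oxidative phosphorylation had a median of -0.27 (adjusted p = 0.000839, adjusted p = 0.53 with an estimated correlation) and fatty acid oxidation -0.40 (adjusted p = 0.00499, adjusted p = 0.53 with an estimated correlation). Enteric neurons had a median of -0.32 (adjusted p = 0.0176, adjusted p = 0.772 with an estimated correlation). The calls of enteric neurons and fatty acid oxidation were lost when some single array of the groups compared was left out. The other 8 held without each of these arrays.

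The interaction asks whether RESUS+VH departs from the sum of the single conditions on the log2 scale. It called 143 genes higher and 98 lower, and the inflammatory, contractile and energy lists did not pass. The interaction equals the difference between the slide pairs, so the combined effect and a pair effect cannot be told apart. The higher share was 59.3%, and without control 4 the count was 365. The count was 3 with normexp on all spots, 68 without spots far below their local background, 4 with the description number as a covariate, 135 with the stricter filter and 678 with array weights. Of the genes the naming rule takes, those above background on some array of every group were Or10q12 (3.69 ± 0.35, adjusted p = 9.3e-05), Eif4g3 (3.08), Qpct (-3.33), Rps26 (-3.16) and Slc4a7 (-2.54). The other 5 had no array well above background in some group, so only bounds can be given and they cannot be ranked. With those groups at the detection floor the log2 value was at least 1.84 for Tp63, 1.502 for Gja6 and 2.36 for Or4g17, and at least as low as -4.79 for Retnlg and -1.998 for Cd300le. Of the 241 genes called, at least 52 (21.6%) had such a group. The Rps26 value may also rest on signal near background, with a control mean of -5.56. So may that of Qpct, with a RESUS+VH mean of -4.68. Rhoa passed as well (1.39 ± 0.22, adjusted p = 0.00591), while Stat3 (-0.89), Nfkbia (0.71), Actg2 (-1.09) and Myh11 (0.23) did not. Immediate early genes were higher (median 0.62, adjusted p = 0.00897, adjusted p = 0.977 with an estimated correlation). Monocyte and macrophage genes (median -0.31, adjusted p = 0.00897, adjusted p = 0.977 with an estimated correlation) and red blood cell genes (median -1.65, adjusted p = 0.00897, adjusted p = 0.977 with an estimated correlation) were lower. Each of these list calls was lost when some single array was left out.

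The comparisons with control share its 4 arrays, so their log2 differences correlate without any effect. Across genes, which are not independent replicates, r was 0.699 between the RESUS+VH and VH comparisons, 0.421 between RESUS+VH and RESUS, and 0.426 between VH and RESUS. Unchanged groups with a shared simulated control, made from residuals of arrays drawn from all 16, gave a median r of 0.508, and up to 0.83. The covariances were 0.288, 0.116 and 0.117, against 0.0673 in the simulations. With the controls split between the comparisons, r was 0.365 to 0.484, 0.009 to 0.203 and 0.033 to 0.202. RESUS+VH and VH shared 734 genes higher and 684 lower, where independent lists would share 86.2 and 111.5. RESUS+VH and RESUS shared 140 and 9, against 11.2 and 4.1, and VH and RESUS shared 74 and 30, against 10.4 and 2.9. Between them 18, 0 and 3 genes were called in opposite directions. With the controls split, and so fewer arrays per comparison, the shared genes numbered 134 to 177 higher and 101 to 163 lower for the first pair. They numbered 25 to 68 and 0 to 2 for the second and 12 to 47 and 9 to 18 for the last. Of called genes with several probes, another probe was called the opposite way for 3 of 471 in RESUS+VH, 6 of 361 in VH and 0 of 8 in RESUS.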

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

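Of the tests in this part, all those on the interaction genes were chosen after the result was seen. The interaction called 241 genes. Values were 3.69 for Or10q12, 3.08 for Eif4g3, -3.33 for Qpct, -3.16 for Rps26 and -2.54 for Slc4a7. That of Rps26 may rest on control signal near background, and that of Qpct on RESUS+VH signal near background. For genes with no array well above background in some group the fitted value rests on signal below detection and only the bound can be read. These were Tp63 (fitted 6, at least 1.84), Gja6 (fitted 5.04, at least 1.502), Or4g17 (fitted 3.33, at least 2.36), Retnlg (fitted -5.38, at least as low as -4.79) and Cd300le (fitted -2.47, at least as low as -1.998). Among the lists, immediate early genes (0.62), monocytes and macrophages (-0.31) and red blood cells (-1.65) were called, with adjusted p = 0.977 for each with an estimated correlation, and each call was lost when some single array was left out. Of 100 splits of all 16 arrays, 2 called as many genes, the real one included, and the highest other split called 1039. That split mostly separates arrays with VH from arrays without it, which points to a structure of the samples. These splits mix VH with no VH and decide nothing on the interaction. Of 50 draws that swap arrays only within a level of VH, 1 called as many, the real one, and the highest other called 88. Of 50 draws that shuffle the residuals of a fit without interaction, 1 called as many, the real one, and the highest other called 1. Chance with the VH effect kept and chance with both effects kept are thus excluded at 0.05, while the slides are not.

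All RESUS+VH arrays lay beyond all others in 32 interaction genes (13.3%). Noise on a single array can break such a separation, so this share does not tell how many genes changed in RESUS+VH alone. Another group can also stand apart, as control did for Rps26 (mean -5.56, others -2.43 to -2.13). A shift between slide pairs may contribute, with no overlap of the pairs in 49 genes (20.3%), but it and a joint effect of RESUS and VH are the same contrast and cannot be told apart. The genes were called by that same contrast, so this share is no separate evidence. The median of the difference within pairs over that between them was 0.537, against 0.347 for the same ratio of the VH effect over 5331 genes. Probes close to background also stay open, with 42.3% of the genes in the lowest quartile of level, against 19.4%, 26.6%, 32.8%, 37.2% and 19.2% in the other comparisons. Olfactory receptor probes were over-represented, with 6 of 364 called against 54 of 9619 other named genes (odds ratio 2.97, Fisher's exact p = 0.0216), and such receptors may mark unspecific signal.

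Single arrays lay far from the other 3 of their group by Dixon's test in 27 of 304 groups checked, where chance gives 15.2 (1 in 20). The spike-in slope was 0.932 on RESUS+VH 4. List scores stood apart for ion channels and calcium handling on VH 4 (-0.60), p53 and apoptosis on RESUS 1 (0.28), mucosal epithelium on control 4 (-2.57, with RESUS+VH 3 at -3.57 and VH 1 at -1.51 also below their groups but not past the test), endothelium on RESUS 4 (-0.49) and oxidative stress on RESUS+VH 4 (0.80). On VH 3 the genes were Cxcl1 (3.47), Fcnb (0.12), Ptges (2.78), Kcnc1 (-4.34) and Klra5 (-2.98). On RESUS+VH 2 they were Fosl1 (-2.26), Steap1 (-0.77), Fcnb (-1.74) and Kcnc1 (-3.77), and on RESUS+VH 1 Omd (-6.30) and Tp63 (-3.47). On control 3 they were Fosl1 (-6.73), Lrrc17 (-3.66), Mmp11 (1.61) and Ptges (-0.25), on control 1 Retnlg (-4.95) and on RESUS 3 Or4g17 (-5.79). On the other VH arrays they were Ccr1l1 (-2.71, VH 1), Il12rb1 (-6.27, VH 2), Dlk1 (-4.17, VH 2) and Or4a2 (-5.44, VH 4).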

How the results depend on the processing

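Counts run in the order RESUS+VH, VH and RESUS against control, RESUS+VH against VH, RESUS+VH against RESUS, and interaction, and were 3498, 2847, 238, 650, 2442 and 241. The epithelium settings, the slide pair block and 3 further forms of normexp were chosen after seeing the data. Normexp on all spots gave 156, 104, 0, 0, 11 and 3. At an unadjusted p of 0.05 (limma) the comparisons with 0 held 652 and 1637 genes. A cause of the loss is 20 spots on RESUS+VH 3 and 5 on RESUS 3 with local background up to 65252 and 40273 around them. They set the fitted background mean to -931 and -621 (2.65 to 9.76 on other arrays) and narrowed the SD of log2 values to 1.11 and 1.27 (1.99 to 2.21 on others). Fitting by maximum likelihood gave 131, 100, 0, 0, 11 and 1 (654 and 1629 unadjusted where 0), and fitting on probe averages 191, 149, 6, 0, 14 and 4 (1731 unadjusted where 0). Leaving out spots more than 50 below local background gave 3276, 2419, 188, 1279, 2138 and 68, with background means of -0.16 and 8.40 and SDs of 2.18 and 2.21. With the last form RESUS+VH against VH and the interaction stayed far from 650 and 241, so those spots do not account for all of the change in these counts. The last form also turned the RESUS+VH against VH calls to mostly lower, and the cause of this was not tested. The median of all genes was 0.154 for RESUS+VH against control with normexp on all spots, -0.138 for RESUS and -0.172 for RESUS+VH against VH without those spots, and -0.128 for RESUS+VH against VH with median normalization. The share of higher calls was 29, 75, 100 and 0% by maximum likelihood for RESUS+VH, VH, RESUS+VH against RESUS and interaction, 30.4, 67.8, 100, 85.7 and 50% on probe averages (without RESUS+VH against VH, which had 0 calls), and 100 and 33.3% for RESUS+VH against RESUS and interaction with normexp on all spots. Stricter filtering tested fewer genes and gave 402 for RESUS+VH against VH and 135 for the interaction. Fits of only the groups compared, with fewer samples, gave 1561, 1181, 141 and 247 for the first 4. Array weights gave 1520 for RESUS, 5220 for RESUS+VH against RESUS and 678 for the interaction. The description number as a covariate gave 1998, 64, 0, 371, 5 and 4 (1172 unadjusted where 0). All numbers of VH and RESUS arrays exceed those of the other groups, so this term overlaps with the slide pairs by construction. The epithelium mean as a covariate gave 389 for RESUS, 985 for RESUS+VH against VH and 561 for the interaction. Without the 3 arrays lowest in epithelium, with fewer samples, the counts were 2013, 1631, 382, 306, 2684 and 395. The slide pair as a block, which takes up the interaction, gave 5330 for VH, 466 for RESUS and 5330 for RESUS+VH against RESUS. For settings where no cause is given, the cause was not tested. Leaving out 1 array gave 1982 to 3582, 1468 to 3071, 119 to 359, 375 to 702, 1147 to 2689 and 163 to 365. The arrays that moved a count by over 1.5 times were RESUS+VH 4 (1982), VH 1, 2 and 4 (1792, 1740, 1468) and control 3 (1806), RESUS 1 to 3 (156, 130, 119) and control 4 (359), RESUS+VH 1 to 3 (428, 375, 416) and VH 1 (408), RESUS+VH 1 and 4 (1321, 1191) and RESUS 1 to 3 (1416, 1147, 1305), and control 4 (365).

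Lists called numbered 16, 17, 2, 4, 10 and 3, and 0 in every comparison with an estimated correlation. Fry gave 0 for RESUS, RESUS+VH against VH and the interaction. For RESUS the number was 1 with quantile normalization, series matrix values, no filter, the stricter filter and the epithelium covariate, 0 without spots far below local background, 4 with array weights and 5 with the description number. It was 12 with normexp on all spots, 13 by maximum likelihood and 11 on probe averages. These 3 forms gave 11 for RESUS+VH against VH, 16 against RESUS and 5 for the interaction. Without spots far below local background 9 lists were called for VH. The slide pair block gave 2 for RESUS+VH against VH and 18 against RESUS. Without the 3 arrays lowest in epithelium the numbers were 14, 17, 4, 10, 15 and 4. Leaving out 1 array gave 13 to 18, 13 to 18, 0 to 6, 4 to 8, 9 to 15 and 1 to 7. The arrays that moved a list count by over 1.5 times were, for RESUS, control 1 (0), 2 (1) and 3 (5) and RESUS 2 (1), 3 (6) and 4 (1), for RESUS+VH against VH RESUS+VH 1 (8), 2 (7), 3 (7) and 4 (8), and for the interaction control 4 (1), RESUS+VH 2 (7), VH 1 (5) and RESUS 3 (1). List medians that 1 array moved by over 1.5 times, beyond those in the account of each comparison, were these. Against control in RESUS+VH they were channels without RESUS+VH 2 (-0.202), endothelium without control 2 (-0.267), immediate early genes without control 4 (0.188) and interferon without RESUS+VH 2 (0.62). In VH they were cell cycle without control 3 (0.214) and control 4 (0.586), interferon without control 4 (0.288), matrix proteases without VH 4 (0.366), and immediate early genes without each single control or VH array (0.094 to 0.347). In RESUS they were immediate early genes without control 1 (-0.202) and ribosomal proteins without RESUS 4 (-0.1). In RESUS+VH against RESUS they were the contractile list without RESUS+VH 4 (-0.311), fatty acid oxidation without RESUS+VH 3 (-0.204) and enteric neurons without RESUS+VH 2 (-0.199). In the interaction they were monocytes without VH 2 (-0.472), VH 4 (-0.176), RESUS 3 (-0.179) and RESUS 4 (-0.478). Of the 52 list calls, 49 remained with series matrix values, 47 with quantile and 51 with median normalization, 30 with fry, 34 with normexp without spots far below local background, 44 with normexp on all spots, 39 with the description number, 43 with the stricter filter and 0 with an estimated correlation. Of 378 calls of named genes, 377, 364 and 364 remained under these, 287 with normexp without spots far below local background and 60 on all spots. Of the named gene calls, 74 of 115, 66 of 110, 7 of 20, 10 of 19, 59 of 103 and 10 of 11 held without each single array of the groups compared. The log2 differences that 1 array moved by over 1.5 times were Omd (-1.264 without RESUS+VH 1) and Gdf15 (0.825 without RESUS+VH 4) in RESUS+VH against control, Cftr (0.506 without VH 1 and 0.665 without VH 3) and Pde1a (-1.298 without VH 2) in VH, and Lats2 (1.113 without VH 2) in RESUS+VH against VH.

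Results whose sign changed, none of them called under the other setting, were these. In RESUS+VH against control, Kcnn2 was 0.095, Stat3 -0.163 and Tek 0.005 with normexp on all spots, 0.094, -0.169 and 0.005 by maximum likelihood, and Kcnn2 and Stat3 were 0.089 and -0.136 on probe averages. Or4a2 in RESUS was 0.04, 0.041 and 0.031 under these. Without spots far below local background Bnc1 was -0.082 in RESUS+VH against control and Efnb1 -0.007 in RESUS+VH against VH. Without those spots the lists of oxidative phosphorylation (-0.176) and ribosomal proteins (-0.209) in RESUS+VH against VH lost their calls (adjusted p = 0.534 and 0.945). The sign of their test changed, but their medians stayed at or below the -0.172 of all genes, so no turn is shown. Ribosomal proteins in RESUS had a median of -0.025, above the -0.138 of all genes, and did not pass (adjusted p = 0.338). Ribosomal proteins were 0.078 in RESUS and 0.002 in RESUS+VH against VH with quantile normalization, and 0.113 in RESUS with the description number. That number gave 0.078 for Lmod1 in VH. With the slide pair as a block Tp63 was 0.286 in VH and -0.322 in RESUS+VH against VH. That block takes up the interaction, so these are averages of the effects over both levels of the other condition and not differences corrected for slide. The correlation of RESUS+VH and VH log2 differences was 0.646 without a filter and averaged 0.433 with the controls split. That of RESUS+VH and RESUS was 0.616 with normexp on all spots and 0.113 with split controls, and that of VH and RESUS was 0.114 with split controls.

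Correlations between arrays did not show a pairing by replicate number, but they cannot exclude one. The 24 same-number pairs had r from -0.487 to 0.2, 6 of them over 0.1. Of 16 arrays 4 correlated best with their own number, about as many as by chance. The highest r (0.617) was between control 4 and RESUS+VH 3, both low in epithelium, so such differences may hide a pairing. With a replicate block the counts were 3252, 2445, 209, 602, 2066 and 192, each within 1.5 times. Slide and scan blocks were not run because each holds a single group. Signal over background limits what dim probes can show, since 66.8% to 73.1% of probes were well above background per group.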

Other observations

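Of the tests in this part, those on mucosal RNA, leukocyte RNA, the clock and other splits of the arrays were chosen after the data were seen. In RESUS+VH against control, further lists held changes in both directions without passing as a whole. Of 22 mechanotransduction genes 3 rose and 4 fell, among them Thbs1 (2.20) and Ankrd1 (-1.66). In water and salt transport 1 gene rose, the aquaporin Aqp9 (0.87), and 3 fell. Against RESUS, Aqp9 (1.85) and the volume-regulated channel subunit Lrrc8a (1.27) rose. In extracellular matrix structure 3 genes rose and 3 fell, with Cspg2, which encodes versican, up by 2.79. In angiogenesis and permeability 5 rose and 3 fell, with endothelin (Edn1) up by 1.64.

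Of the 35 splits of the 8 arrays in each pairwise comparison, only the real one, 1 split, called as many genes in each. The highest other splits called 1 for RESUS+VH against control (real 3498), 13 for VH (2847), 1 for RESUS (238), 59 for RESUS+VH against VH (650) and 3 for RESUS+VH against RESUS (2442). Chance is thus excluded at 0.05 for these counts, while the slides are not.

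In RESUS+VH against control 6 lists of muscle, energy, nerve and endothelium were lower, with mean shifts from -0.33 to -0.52 and a mean of -0.41, but 0 were called with an estimated correlation (smallest adjusted p = 0.489 with an estimated correlation), and the endothelium call was lost without control 1 (adjusted p = 0.0741), control 2 (0.0509) or RESUS+VH 2 (0.104). Mucosal RNA carried over in other amounts would lose the shift once epithelium is a covariate, and 98.7% of it was left (-0.40). The mean epithelium score was 0.03 ± 1.75 (SD) in control and 0.09 ± 2.53 in RESUS+VH. With means so alike the covariate could hardly change the shift, so the 98.7% adds little to these scores. Leukocyte RNA diluting muscle RNA would lower contractile genes alike if muscle were their only source. Of 18 compared, 4 departed from the list median, with Smtn at -1.04, Lmod1 at -0.82, Dmn at -0.55 and Vcl at 0.66. An equal fall of all members was thus not seen. Dilution stays open, since members that other cells also express would fall less under it. The other lists were not tested for dilution. A shift of single slides cannot be told apart from the groups. On the other slide pair, VH minus RESUS gave medians of -0.37 for contractile, -0.26 for channel and -0.26 for fatty acid genes. It gave -0.21 for neuron genes, -0.02 for oxidative phosphorylation and 0.02 for endothelium (mean of all 6 -0.18). The inflammatory and STAT3 lists had 1.83 and 1.63. This is another contrast, since it subtracts any effect of RESUS, which RESUS+VH against control includes. The values for oxidative phosphorylation and endothelium thus do not show that their fall was absent.

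The circadian clock list did not pass in VH (adjusted p = 0.951) or RESUS+VH (adjusted p = 0.89), but its arms differed in VH, where the mean of 4 genes of the activator arm was 1.36 higher than in control and that of 9 output genes -0.73, each with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give in a two-sided test. The arm names do not give the role of each member. Nfil3 is an output gene grouped here by its expected phase, Cry1 is a repressor, and the output arm holds repressors such as Nr1d1. The upper arm rests on Nfil3 (3.13) and Bmal1 (1.90), while Cry1 (0.22) and Npas2 (0.21) did not pass. Without Nfil3 it was 0.78 (exact p = 0.0286), and of the output genes Dbp and Bhlhe41 passed but Nr1d1 (-0.47, adjusted p = 0.319) did not. Tissue collected at another hour may account for the difference between the arms of 2.09, although the labels give no hour and an effect of VH or of the slide on these few genes stays open. In RESUS+VH the difference of 1.49 decides nothing, since without Nfil3 (2.94) the activator arm was 0.25 (exact p = 0.0571), Bmal1 did not pass (0.36, adjusted p = 0.517), and Bmal1 and Nr1d1 were both lower than in VH (-1.55 and -1.54). Of the output genes Bhlhe41 (-1.78), Dbp (-1.44) and Nr1d1 (-2.01) passed in RESUS+VH and the others did not. Their arm was -0.57 (exact permutation p = 0.0571).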
